A study of Mus musculus with 4 samples.

How the data were processed

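Hi-C, which ligates and sequences DNA fragments that lie close together in the nucleus, was made from female mouse tail tip fibroblasts (TTF) of mus/cas hybrid animals. The 4 samples were 2 wild-type (WT) and 2 Sirt7-/- (KO) replicates. Per the labels' protocols, cells were fixed with 2% formaldehyde, chromatin was cut with HindIII, the ends were filled in with biotin and ligated in the nucleus. The series' design text names an assay of Xist binding, whereas the sample labels and the file headers describe Hi-C, and the values were treated as Hi-C.

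The 8 deposited matrices cover chromosome X, 1 for each genotype, allele and bin size (250 kb and 100 kb). Each value is a score, a correlation coefficient between the contact profiles of a pair of bins, and the authors combined the replicates of a genotype and split reads by allele before making it, per the file headers. The headers give the HOMER matrix format, and the submitters' processing notes name cutadapt, Bowtie2, HOMER, Juicer and the build mm10, with versions not given. The contact normalization that preceded the correlation, the rule for assigning reads to alleles and the number of reads are not given in the sources used here. Depth is therefore unknown, and the correlation of adjacent bins and the SD of the entries were used as stand-ins. Noise from low depth shrinks correlations, and smaller bins hold fewer reads.

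With the replicates combined, no comparison between genotypes has a replicate check, and no significance test between the genotypes, p-value or standard error was computed. Ranges in parentheses beside contrasts, matrix similarities and list medians are from leaving out each of 17 blocks of 10 Mb in turn, and the other values are given without a spread. That range shows how far any single block moves a value. The 17 values share most of their data, so the range is narrower than the spread between blocks. It is not a confidence interval and does not describe spread between cultures. Bins without data in any of the 4 matrices of a bin size were left out, leaving 588 of 683 bins at 250 kb and 1461 of 1707 at 100 kb. Main values are from 250 kb bins and pairs at least 2 Mb apart, except boundary scores and long-range pairs, which are from 100 kb bins.

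The megadomain contrast was the mean correlation of pairs on the same side of the bin holding the midpoint of 4933407K13Rik, the host transcript of the Dxz4 macrosatellite, minus that of pairs across it at equal distance. It was also computed for a split at every bin at least 20 Mb from either end. The A/B contrast was the mean correlation of pairs within class A or within class B minus that of pairs between classes. A and B were the 20% of bins at either end of the first principal component of the mean cas matrix, A being the end with more genes. The compartment score of a bin was its mean correlation with A bins minus that with B bins. The boundary score was the mean correlation within 1 Mb on each side of a bin minus that across it. Pairs on a side lie closer than pairs across, so this score is not matched on distance. Long-range pairs were averaged over squares of 3 by 3 bins and ranked among squares within 1 Mb of the same distance.

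Genes were placed by their midpoints from the RefSeq annotation of the same build, and 6 gene lists were fixed before the data were examined: structural loci, escape genes, silenced genes, fibroblast genes, neuronal genes, and testis and placenta clusters. List medians were ranked among 10000 random lists of bins matched on gene number, giving 12 percentiles over both alleles. They were ranked again among random lists matched also on the side of Dxz4, a choice made after the data were seen. Random bins were drawn singly, whereas some listed genes lie in adjacent bins, whose differences on mus were correlated. The percentiles of such lists can be too extreme. The genes named are all structural loci, the 2 highest and 2 lowest of every other list by KO minus WT compartment score on mus, and the 3 highest and 3 lowest gene-holding bins per allele whose change had the same sign at 100 kb. A gene that this rule selects is not reported here. Other genes named were chosen after their values were seen.

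Alternatives were the other bin size, a minimum distance of 5 Mb, division of each matrix by its SD, subtraction of the mean of each distance, omission of the weakest bins, other splits and classes, rank correlation, and other windows and squares. The functions were tested on simulated matrices over the 588 bins. The largest error was 0.000602 for the megadomain contrast and 0.000791 for the A/B contrast, and 100% of 50 planted bins were recovered. The planted shifts were larger than the differences seen on mus, and the simulated noise was independent between bin pairs. The recovery therefore does not show that differences of the size seen on mus would be found. A simulated compartment pattern with no megadomains gave a megadomain contrast of -0.0112 at the strength measured on WT cas and -0.00034 at that on WT mus. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.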

Results

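Chromosome X folding was measured by Hi-C in female hybrid tail tip fibroblasts, with 2 WT and 2 Sirt7-/- (KO) replicates. SIRT7 is a nuclear NAD-dependent deacylase of the sirtuin family. The hybrid genome allowed reads to be assigned to the mus or the cas copy of the chromosome, so that each copy had its own correlation matrix in each genotype. The labels do not state which copy was inactive. The replicates of each genotype were combined before deposit, so the differences below have no replicate check and describe these matrices only. Ranges in parentheses are the lowest and highest value when each 10 Mb block was left out, and are not confidence intervals. Read depth is unknown. The mean correlation of adjacent 250 kb bins, a stand-in for it, was 0.149 in WT and 0.131 in KO on mus, and 0.196 and 0.184 on cas. On cas this order turned at 100 kb, with 0.0690 in WT and 0.0716 in KO.

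The first comparison asked whether the split of chromosome X at Dxz4 differed between WT and KO. Dxz4 is a macrosatellite at which the inactive X is known to part into a pair of large domains. On the mus chromosome, regions on the same side of Dxz4 had more similar contact profiles than regions across it, and this contrast was 0.0284 (0.0212 to 0.0370) in WT and 0.0165 (0.0101 to 0.0244) in KO. The KO to WT ratio was 0.580 (0.417 to 0.750). On mus, pairs across Dxz4 had a mean correlation of -0.0128 in WT and 0.00522 in KO, and pairs on the same side had 0.0155 and 0.0217. On cas the contrast over all distances was negative, -0.0363 in WT and -0.0282 in KO.

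The KO minus WT difference was -0.0119 (-0.0173 to -0.00528) on mus and 0.00812 (-0.000547 to 0.0149) on cas, and the mus change minus the cas change was -0.0200 (-0.0268 to -0.0135). The contrast was positive on mus and negative on cas, so an equal proportional shrinkage on both would also make this last value negative. It therefore does not show a change particular to mus. Without the block from 80 to 90 Mb, next to the block that holds Dxz4, the mus difference was -0.00528. Without the block from 60 to 70 Mb the cas difference was -0.000547, and without that from 70 to 80 Mb it was 0.0149. At 100 kb the mus contrast was 0.0109 in WT and 0.00954 in KO, a ratio of 0.872 (0.772 to 0.968), so the size of the difference depended on the bin size.

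Among 449 possible splits of the chromosome, the bin of Dxz4 (chromosome X, 75500001 to 75750000, mm10) ranked 4 in WT mus and 3 in KO mus. The highest contrast on mus lay in the adjacent bin, 75250001 to 75500000, in both genotypes. The position of the split was therefore the same to the bin in WT and KO. On cas the Dxz4 bin ranked 375 in WT and 382 in KO, and the highest contrasts lay at 129 Mb and 128.75 Mb.

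**Figure D1:**
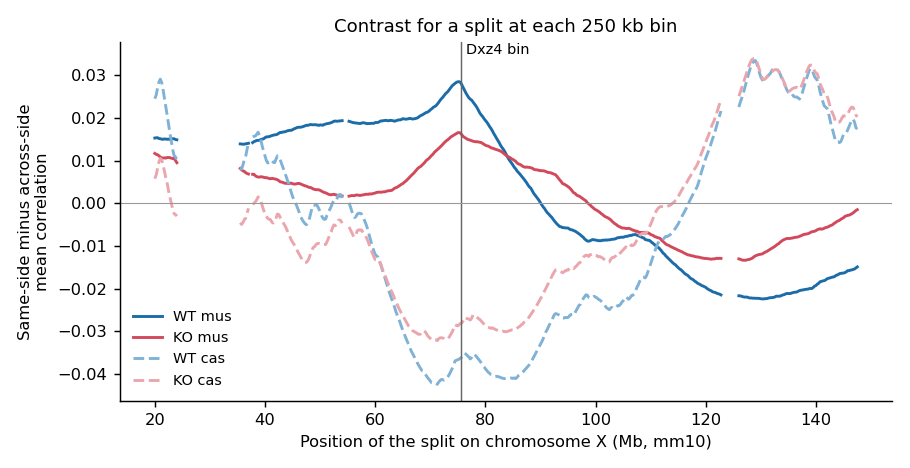
Same-side minus across-side mean correlation (y axis, correlation units) for a split at each 250 kb bin of chromosome X (x axis, Mb), with solid lines for mus and dashed lines for cas in WT and KO. Both mus lines are highest at 75.25 Mb, next to the Dxz4 bin, at 0.0285 in WT and 0.0166 in KO, and the cas lines are below 0 at Dxz4.

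Among distances from 2 Mb up, the difference on mus was largest for the closest pairs. For pairs 2 to 5 Mb apart the mus contrast was 0.107 in WT and 0.0347 in KO, a ratio of 0.325, and at 100 kb this ratio was 0.294. The ratio on mus was 0.572 at 5 to 10 Mb, 0.630 at 10 to 20 Mb and 0.650 at 20 to 50 Mb, and at 100 kb it was 0.635, 0.738 and 0.761. On cas the contrast of close pairs was positive too, 0.0971 in WT and 0.0750 in KO at 2 to 5 Mb and 0.0692 and 0.0409 at 5 to 10 Mb. The cas ratio was 0.773 at 2 to 5 Mb, and 0.909 at 100 kb, and 0.591 at 5 to 10 Mb, close to that of mus. The 2 to 5 Mb values rest on 150 pairs across Dxz4 at 250 kb, against 6258 on the same side. Beyond 50 Mb the mus contrast was -0.0123 in WT and -0.0112 in KO, and at 100 kb it was -0.00204 in WT and 0.00147 in KO. Below 2 Mb the mus contrast was 0.0420 in WT and -0.0245 in KO, with 21 pairs across Dxz4. At 100 kb it was negative in both genotypes below 2 Mb, -0.0120 in WT and -0.0328 in KO, with 161 pairs across.

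**Figure D2:**
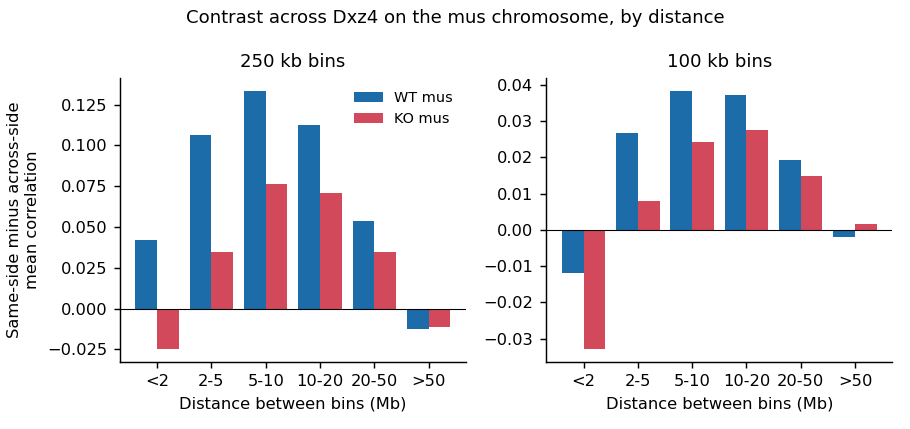
Same-side minus across-side mean correlation on the mus chromosome (y axis, correlation units) by distance between bins (x axis, Mb), for 250 kb and 100 kb bins, with a bar for WT and a bar for KO. From 2 to 50 Mb the KO bars are shorter than the WT bars at both bin sizes, and below 2 Mb the across-side values come from 21 pairs at 250 kb.

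The boundary at Dxz4 itself was also lower in KO on mus. Its boundary score was 0.0416 in WT, at the 99.5 percentile of 1385 bins, and 0.0219 in KO, at the 98.0 percentile. The change lay at the 0.289 percentile of all bins. Shrinkage of all scores by a single factor would lower the highest WT scores most, so this rank alone does not set Dxz4 apart. With a 500 kb window the score on mus was 0.0449 in WT and -0.00404 in KO, and with a 2 Mb window 0.0467 and 0.0331. On cas the score at Dxz4 was lower in KO too, 0.0236 in WT and 0.0108 in KO, at the 68.7 and 40.5 percentiles. The change on cas lay at the 3.90 percentile. Firre, a long noncoding RNA locus (50563120 to 50635321), had a boundary score on mus of 0.0249 in WT and 0.00788 in KO, but at 500 kb the values were 0.0107 and 0.00724 and at 2 Mb 0.0124 and 0.0105. The bin shared by Xist, the RNA that coats the inactive X, and its antisense partner Tsix had scores of 0.00176 and -0.00221 on mus, but -0.0187 and 0.00338 with a 500 kb window and 0.00259 and 0.00263 with 2 Mb. The 11 scored escape-gene bins had a median score on mus of 0.00250 in WT and 0.00244 in KO, against 0.00344 and 0.00387 over all bins.

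Dxz4 and Firre, which lie 25.2 Mb apart, ranked low on mus among pairs of like distance at 100 kb. Their mean correlation on mus was -0.0614 in WT and -0.0577 in KO, at the 0.0456 and 0.0290 percentiles of 24133 squares at like distance. With single 250 kb bins the mus percentiles were 10.3 and 0.988. On cas the pair lay at the 38.0 and 32.3 percentiles. Dxz4 and Xist lay at the 89.9 percentile in WT and the 92.0 in KO on mus, and Firre and Xist at the 63.6 and 32.0 percentiles. With single 250 kb bins these were 79.5 and 47.9 for Dxz4 and Xist, and 41.8 and 53.4 for Firre and Xist, so that both directions turned.

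The second comparison asked whether A and B compartments, the gene-rich and gene-poor sets of regions that contact their own kind, differed between WT and KO. The 118 A bins held 340 protein-coding genes and the 118 B bins held 55. On the cas chromosome the A/B contrast was 0.357 (0.349 to 0.366) in WT and 0.315 (0.309 to 0.323) in KO, a ratio of 0.885 (0.877 to 0.890). On the mus chromosome the A/B contrast was weak, 0.0108 in WT and 0.0138 in KO, and the ratio of 1.28 ranged from 0.759 without the block from 60 to 70 Mb to 1.77 without that from 110 to 120 Mb. At 100 kb the ratio was 0.886 on cas and 0.813 on mus, and with classes from mus it was 0.824 on mus, so that the direction on mus turned in both settings. Dividing each matrix by the SD of its entries brought the cas ratio to 0.997.

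The cas matrices of WT and KO were alike, with a correlation over bin pairs of 0.852 (0.835 to 0.859), and the mus matrices less so, with 0.512 (0.493 to 0.534). At 100 kb these were 0.533 and 0.175. Within a genotype, the mus and cas matrices correlated at 0.0974 in WT and 0.107 in KO. Bin pairs are not independent replicates, and noise lowers such correlations more where a chromosome has less structure, as on mus.

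By distance, the mean correlation of pairs 2 to 5 Mb apart on mus was 0.113 in WT and 0.0945 in KO, and that of pairs 20 to 50 Mb apart was 0.0105 and 0.0193. On cas the same classes had 0.0941 and 0.0858, and 0.0419 and 0.0392.

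The compartment scores of WT and KO followed each other closely on cas and less closely on mus. On cas, 37 of 588 bins (6.29%) changed sign, and the scores of WT and KO correlated at 0.964. On mus, 204 bins (34.7%) changed sign, with a correlation of 0.427, but the scores on mus lay near 0, with a median size of 0.0164 in WT against 0.279 on cas. The share on mus was 22.8% without the block from 80 to 90 Mb and 39.1% without that from 70 to 80 Mb, which holds Dxz4. On mus the KO score was lower in 195 of 231 bins left of Dxz4, with a median difference of -0.0222, and higher in 276 of 356 bins right of it, with a median of 0.0116.

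**Figure D3:**
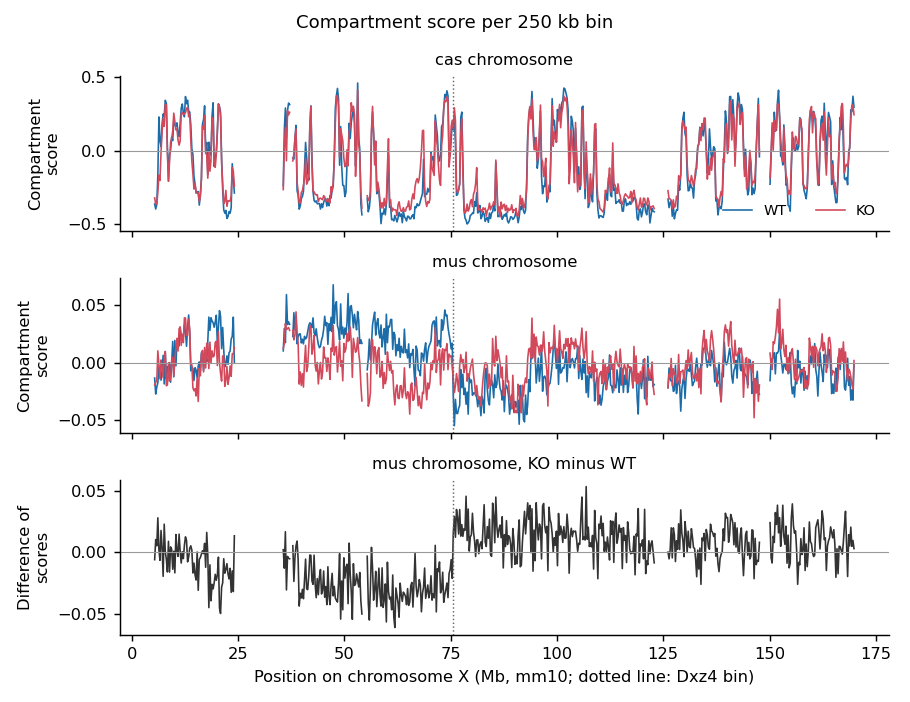
Compartment score per 250 kb bin (y axes, correlation units) along chromosome X (x axis, Mb) on cas and on mus in WT and KO, and the KO minus WT difference on mus. The difference on mus steps from a median of -0.0222 left of the Dxz4 bin to 0.0116 right of it, and the scales of the panels differ.

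Most bins of genes that escape X inactivation had a lower score on cas in KO. The split at Dxz4, known from the inactive X, stood out on mus and not on cas. The difference thus lay on the copy that did not show this split, and it does not show a change of escape from inactivation. Of 12 escape-gene bins, 11 had a lower cas score in KO, with a median difference of -0.0547 (-0.0610 to -0.0493), at the 0.91 percentile of matched random lists. With 100 kb bins the median difference was -0.0180. Scores are smaller at that bin size, with a WT cas A/B contrast of 0.0951 against 0.357 at 250 kb. The sizes of these medians are therefore not comparable. Since the A/B contrast on cas was lower in KO over all bins, the list was also ranked after division by the SD, where 10 of 12 bins were lower and the percentile was 1.27. Among random lists matched also on the side of Dxz4 it was 1.11. Shroom4, an actin-binding protein gene, went from 0.0697 to -0.203 on cas and Car5b, a mitochondrial carbonic anhydrase gene, from 0.230 to 0.0954. The bin of Ftx went from 0.201 to 0.0624 and that of Xist, Tsix and Jpx from 0.235 to 0.141, and both bins also belong to the structural list. These bins adjoin, so they are not separate observations. The next bin, that of Rlim from the silenced list, fell too, from 0.130 to -0.0472 on cas. The drop in this region was therefore not particular to escape genes. Firre was the escape locus with a higher cas score in KO, at -0.0836 in WT and 0.00658 in KO. On mus the escape bins had a median difference of 0.00511 (-0.00761 to 0.0102), at the 59.1 percentile. The histone demethylase genes Kdm6a and Kdm5c differed in direction on mus, with -0.0450 for Kdm6a left of Dxz4 and 0.0282 for Kdm5c right of it. Utp14a had a difference of -0.0405 and Eif2s3x, a translation initiation factor gene, of 0.0354.

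The 4 structural bins had a median difference of 0.0144 on mus (85.4 percentile, or 78.3 when matched also on side) and -0.0429 on cas (-0.0962 to 0.0507), where 2 bins were higher and 2 lower. The cas median was 0.0174 at 100 kb and 0.00339 without the weakest bins. The bin of the Dxz4 host transcript (75725458 to 75764699) had scores of -0.0304 in WT and -0.0142 in KO on mus.

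Genes silenced on the inactive X had a lower cas score in KO in 9 of 11 bins, with a median of -0.0328 at the 22.9 percentile, and a median of 0.0103 (-0.0247 to 0.0194) on mus. After division by the SD the cas median was 0.0491. On mus, Atrx, a chromatin remodeller gene, had a difference of 0.0449 and Huwe1, a ubiquitin ligase gene, of 0.0383, and G6pdx, the gene of glucose-6-phosphate dehydrogenase, had -0.0369. Fmr1 had a difference of -0.0283 on mus and 0.197 on cas.

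Fibroblast genes were lower in KO on mus in 7 of 10 bins, with a median of -0.0172 (-0.0260 to -0.00220) at the 2.66 percentile. Of these bins 7 lie left of Dxz4, and among random lists matched also on side the percentile was 13.6. Timp1, a metalloproteinase inhibitor gene, went from 0.0406 to -0.00924 and Bgn, which encodes the matrix proteoglycan biglycan, from 0.0342 to -0.00648, and both lie left of Dxz4. The basement membrane collagen gene Col4a6, right of Dxz4, had a difference of 0.0238. Plp2, left of Dxz4, went against its side with 0.0228. On cas the fibroblast list had a median of -0.0161, and 0.106 after division by the SD.

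Neuronal genes had median differences of 0.000649 on mus and 0.0102 on cas, at the 41.2 and 39.6 percentiles, or 6.85 and 38.3 when matched also on side, and after division by the SD they were -0.00202 and -0.0274. Pcdh11x had a difference of 0.0349 on mus, whereas Gabra3, a GABA receptor subunit gene, had -0.0330 and Gria3 had -0.0191. The testis and placenta clusters, with 27 bins, had a median of -0.00887 on mus at the 1.37 percentile, or 4.89 when matched also on side. Without the weakest bins the median was 0.00131. Many of these bins are adjacent, and differences of adjacent bins on mus correlated at 0.619. Random lists drew bins singly, so these percentiles can overstate how unusual the list is. On cas the median was 0.00576 (-0.0117 to 0.0145), 0.0542 without the weakest bins and -0.135 after division by the SD. Xlr3c and Xlr5c share the bin of Bgn at -0.0407, and Mageb18 and Magea7-ps had 0.0333 and 0.0348.

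Among gene-holding bins whose difference had the same sign at 100 kb, those with the lowest KO minus WT score on cas were that of Bmp15 at 6.25 Mb, from 0.230 to -0.168, that of Gprasp1, Gprasp2 and Bhlhb9 at 135.75 Mb, from 0.149 to -0.163, and that of Shroom4 at 6.5 Mb. The highest on cas were those of Olfr1320 and Olfr1321 at 49.5 Mb, from -0.237 to 0.0680, of 4933436I01Rik at 67.75 Mb, and of Heph and Gpr165 at 96.5 Mb, from -0.294 to -0.0737. On mus the lowest were a bin of Gm6664, 3830403N18Rik and Gm35586 at 55.75 Mb (-0.0551), that of Usp26 at 51.75 Mb (-0.0546) and that of Enox2 at 49 Mb (-0.0544). The highest on mus were the bins of Rtl3 and Lpar4 at 106.75 Mb (0.0534), of Prrg1 and Fam47c at 78.5 Mb (0.0455), and of Fgf16, Atrx and Magt1 at 105.75 Mb (0.0449). The 3 lowest on mus lie left of Dxz4 and the 3 highest right of it.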

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

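The tests of the 100 kb contrast, of a single noise factor on mus and on cas, of shrinkage, of misassigned alleles and of the A/B contrast on cas were chosen after the results were seen, and the SD of each matrix was known before any noise test was written. The results given here went one way between WT and KO on mus and the opposite way on cas. With 1 combined matrix for each genotype and allele, none of these differences between alleles was tested. The megadomain contrast differed by -0.0119 on mus and 0.00812 on cas, but it was positive on mus and negative on cas and moved toward 0 on both, with KO to WT ratios of 0.580 and 0.776. For pairs 2 to 5 Mb and 5 to 10 Mb apart it was lower in KO on cas as well, with differences of -0.0221 and -0.0283.

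A noisier KO library would lower the megadomain contrast on mus with the other structure of the matrix, but at 250 kb the KO to WT ratio was 0.662 (0.478 to 0.848) after division by the SD and 0.662 (0.483 to 0.858) relative to the neighbour correlation. Shrinkage of every correlation toward 0 by a single factor would lower the positive same-side mean. That mean was higher in KO by 0.00615 (0.00428 to 0.00942) at 250 kb and by 0.00229 (0.00159 to 0.00338) at 100 kb. At 250 kb the rise came from pairs over 20 Mb apart. There same-side pairs 20 to 50 Mb apart went from 0.0234 in WT to 0.0280 in KO, away from 0. Shrinkage of all pairs alone is therefore argued against at 250 kb. At 100 kb the rise came from pairs over 50 Mb apart, which were negative in WT (-0.00429) and positive in KO (0.00187). Shrinkage would give part of that rise, so it does not decide at 100 kb, where the ratio to the neighbour correlation was 1.00 (0.898 to 1.12). Closer same-side pairs were lower in KO, so they do not argue against shrinkage of closer pairs. Pairs across Dxz4 moved toward 0 in KO from 5 to 50 Mb at both bin sizes, as under shrinkage. From 2 to 5 Mb they rose away from 0, from 0.00711 to 0.0585 at 250 kb and 0.00203 to 0.0138 at 100 kb. Shrinkage alone would not give that rise, but the means rest on 150 and 952 pairs and have no range. At 100 kb shrinkage or a noisier library that also shifts all pairs stays open. There division by the SD gave 0.916 (0.815 to 1.01), and pairs 5 to 50 Mb apart gave 0.859 (0.786 to 0.918) relative to the neighbour correlation. Reads of cas counted as mus in KO would have raised the A/B contrast on mus too, but it closed 0.863% of its gap to cas against 18.4% for the megadomain contrast, a quotient of 0.0469 (-0.0317 to 0.208) that argues against mixing if mixing is linear. A weaker split at Dxz4 without SIRT7 is a hypothesis that these matrices leave open and untested against culture-to-culture spread.

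The A/B contrast differed by 0.00298 (-0.00401 to 0.00679) on mus and -0.0411 on cas, but at 100 kb it was lower in KO on both, with ratios of 0.813 and 0.886. After division by the SD the cas ratio was 0.997, but the compartment pattern makes up 63.4% of the variance there, so the division removes a change in it by construction and the test decides nothing. Relative to the neighbour correlation the cas ratio was 0.946 (0.935 to 0.954) at 250 kb, near what a single noise factor gives, and 0.854 (0.837 to 0.863) at 100 kb, where the neighbour correlation was higher in KO. A single noise factor is thus argued against at 100 kb and stays open at 250 kb, beside weaker compartments, which were not tested between cultures.

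The mean correlation of all pairs at least 2 Mb apart differed by 0.00247 on mus and -0.00352 on cas. For pairs 10 to 20 Mb apart the Dxz4 contrast differed by -0.0416 on mus and 0.0211 on cas, and for 20 to 50 Mb by -0.0188 and 0.00843. The cas contrast was negative in both classes and weaker in KO. It was -0.0934 in WT and -0.0723 in KO at 10 to 20 Mb, and -0.0349 and -0.0264 at 20 to 50 Mb. The median compartment score differed by 0.0144 on mus and -0.0429 on cas for structural loci, by 0.00511 and -0.0547 for escape genes, by 0.0103 and -0.0328 for silenced genes, and by -0.00887 and 0.00576 for testis and placenta clusters. The alleles went the same way for structural loci at 100 kb (0.00675 and 0.0174) and without the weakest bins (0.00951 and 0.00339), for testis and placenta clusters without the weakest bins (0.00131 and 0.0542), and after division by the SD for these clusters (-0.138 and -0.135) and silenced genes (0.194 and 0.0491). The boundary score differed by -0.0171 on mus and 0.00654 on cas at Firre, and by -0.00396 and 0.00266 at Xist. With windows of 500 kb and 2 Mb the mus difference at Firre was -0.00350 and -0.00188, and Xist had 0.0221 and 0.00198 with 500 kb, the same direction, and 0.0000427 and -0.00164 with 2 Mb, where both signs turned.

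Among bins of the list genes named above, the score was higher in KO on mus and lower on cas for Xist (0.0195 and -0.0937), Ftx (0.0126 and -0.139), Car5b (0.0117 and -0.135), Kdm5c (0.0282 and -0.00672), Eif2s3x (0.0354 and -0.0510), Huwe1 (0.0383 and -0.0136), Atrx (0.0449 and -0.0328), Plp2 (0.0228 and -0.0693) and Col4a6 (0.0238 and -0.101). It was lower on mus and higher on cas for Firre (-0.00973 and 0.0902), Fmr1 (-0.0283 and 0.197), Bgn (-0.0407 and 0.0148) and Gria3 (-0.0191 and 0.0398). The score differences on mus carry the step at Dxz4.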

How the results depend on the processing

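Pairs 5 to 50 Mb apart, the 100 kb matrices divided by their SD and the list percentiles after that division or matched on side were chosen after seeing the data. No paired analysis was possible because the replicates of each genotype were combined in the deposited matrices, and leaving out each replicate was not run for the same reason. The megadomain ratio on mus was below 1 in every setting tried with all blocks kept, at 0.495 without the weakest bins, 0.872 at 100 kb and 0.916 at 100 kb after division by the SD (up to 1.01 with a block left out), and for pairs 5 to 50 Mb apart it was 0.640 at 250 kb and 0.749 at 100 kb. On cas this ratio was 0.700 at 100 kb, 0.676 there for pairs 5 to 50 Mb apart, 0.721 without the weakest bins and 1.62 without distance matching. The A/B ratio on mus was 2.07 for pairs at least 5 Mb apart and 1.80 with the mean of each distance subtracted, but 0.813 at 100 kb, 0.847 there after division by the SD and 0.824 with classes from mus. On cas it was 0.997 after division by the SD, 0.947 after that at 100 kb, 0.891 with the mean of each distance subtracted, 0.876 without the weakest bins, 0.827 with all bins split between the classes, and 0.826, 0.946 and 0.726 with classes from WT cas, KO cas and mus. Classes taken from a matrix favour that matrix, so the size on cas depends on the class source. The WT to KO correlation on mus was 0.175 at 100 kb, 0.485 for pairs at least 5 Mb apart, 0.423 with the mean of each distance subtracted, 0.572 without the weakest bins and 0.482 by ranks, and on cas it was 0.533 at 100 kb and 0.885 without the weakest bins. The neighbour ratio on cas turned to 1.04 at 100 kb. The change of the boundary score at Dxz4 was -0.0489 on mus with a 500 kb window and -0.0136 with 2 Mb, and 0.000336 on cas with 2 Mb. At Xist on mus it turned to 0.0221 with 500 kb. Apart from left-out blocks, the list medians that turned were testis and placenta clusters on mus (0.00131) and structural loci on cas (0.00339) without the weakest bins, structural loci on cas at 100 kb (0.0174), neuronal genes on mus with classes from KO cas (-0.00270), and, after division by the SD, which also changes their unit, neuronal genes on mus (-0.00202) and silenced (0.0491), fibroblast (0.106), neuronal (-0.0274) and testis and placenta lists (-0.135) on cas. The causes were not tested. Unknown depth limits every comparison, and smaller bins hold fewer reads.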

Other observations

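The comparison of mus with cas scores after removal of the side means was written before its value was seen, but after the step at Dxz4 had been seen. The same comparison at 100 kb was chosen after the result was seen, and the test of adjacent bins was planned before its result.

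The compartment score on mus resembled that on cas more in KO than in WT. The correlation of mus with cas scores over bins was 0.330 in WT and 0.550 in KO, and 0.217 and 0.308 at 100 kb. A candidate explanation is that the step at Dxz4 in WT covers a compartment pattern that both genotypes hold on mus. After the mean score of each side was subtracted, the correlations were 0.421 and 0.552, a difference of 0.131 (0.0915 to 0.176), so removing the step took away part of the difference and left a part that did not clear the bound of 0.1 for every left-out block. At 100 kb the correlations after subtraction were 0.253 and 0.316, a difference of 0.0627 (-0.00947 to 0.0836), but the difference lay under 0.1 before subtraction too, so that bin size decides nothing. Independent noise of single bins would leave adjacent KO minus WT differences on mus uncorrelated, but they correlated at 0.619 against -0.172 to 0.135 in 1000 shuffles, which a step alone would also give.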
